A study of Homo sapiens with 8 samples.

How the data were processed

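Per the submitters' processing notes, RNA was isolated with a Qiasymphony kit, libraries were made with the NEBNext Ultra II RNA kit, reads were trimmed with Trimmomatic 0.36 and aligned to GRCh38 with STAR 2.5.2b, and gene counts came from featureCounts of Subread 1.5.2. The annotation release and the strand setting of the counting were not given in the sources used here. The authors deposited a table of gene counts and a table of TPM, and both covered 57500 genes and 8 libraries. The deposited TPM were counts divided by a fixed length per gene: 0 of 8044 genes with at least 200 counts in every library differed by more than 0.1% between libraries. Reads were not used here.

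Genes were matched to GENCODE 29 by identifier (56898 matched, 602 not), which gave type, position, length and GC content. Of the symbols, 485 were missing and stayed so, and 27 looked like dates and were replaced from the annotation. Groups came from the current sample titles. The description field holds earlier titles that assign mitoT-EC and mitoAT-EC differently, and the series text says the titles were updated. Whether the libraries of a group are separate cultures or donors, and whether groups share donors, was not stated, so p-values measure only the spread between these samples. All 8 libraries were kept.

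Counts were tested in edgeR 4.0.16 (R 4.3.3) with filterByExpr (18473 genes), TMM scaling and a quasi-likelihood fit of the 8 libraries with 3 groups and no covariate (common dispersion 0.103). A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested, in two-sided tests. The standard error is the absolute log2 fold change divided by the square root of F. Unadjusted counts, where given, are from the same edgeR fit. DESeq2 1.42.0 and limma 3.58.1 served for other settings. Gene lists (35 fixed, 33 with at least 5 tested members, 968 of 971 entries matched) were tested with camera at a preset correlation of 0.01, adjusted over the lists, and with an estimated correlation and fry as other tests. Members were counted as called over all genes and also with the adjustment made over the list alone. CPM are from edgeR with TMM-scaled totals. Those of the HEK293 markers, of the olfactory receptor genes and of the mtDNA gain per kilobase instead used raw library totals.

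Groups, comparisons, tests, gene lists, marker lists and the rule for which genes to name were chosen before the data were examined. The rule took up to 10 genes per direction with the largest fold change among called genes that had a mean of at least 5 CPM in the higher group and libraries that did not overlap. It added up to 4 members of each called list and a fixed set of mitochondrial, mitophagy, endothelial and stromal genes. Some genes that this rule covers are not reported here. Because mitoT-EC against unprimed-EC gave few calls, a rule of the same size was also run on the calls with the block. There each mitoT-EC library had to differ in 1 direction from the unprimed-EC library of its number, and the groups could overlap, as they did for MT2A, CCNA1 and ELMOD1. MALAT1, the RNA classes and the HEK293 markers were added after seeing the data.

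The pairing check compared libraries after removing group means. Deviations of mitoT-EC and unprimed-EC libraries with the same number correlated at 0.428, 0.385 and 0.543, and those with different numbers at −0.34 to −0.15. Removing group means from 3 libraries ties these values together, so positive same-number values push the others down. The check thus favoured pairing by number in these groups but did not establish it. Values with the replicate number as a block are printed beside the unblocked ones. For mitoAT-EC the same-number values were 0.402 and 0.0578 against unprimed-EC and 0.362 and −0.0571 against mitoT-EC, which does not show pairing. Deviations of 2 libraries from their mean mirror each other, so this check could hardly show it. MitoAT-EC replicate 2 correlated most with replicate 3 of unprimed-EC (0.423) and of mitoT-EC (0.426). The block still places it with replicate 2, so mitoAT-EC values with the block rest on a pairing that was not shown. The simulation of unchanged groups with pairing was added after seeing the data. It gave mitoT-EC and unprimed-EC libraries of the same number a shared part at the mean observed correlation, 0.452, and reached 0.395 in the simulated counts.

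Shares of counts are per library, and groups were compared with an exact two-sided permutation test of the difference of means, whose lowest p is 0.1 for 3 libraries against 3 or 2. The 95% Wilson intervals of the mtDNA shares were 6.563 to 6.584, 4.446 to 4.463 and 3.649 to 3.655% in unprimed-EC, 7.112 to 7.130, 2.656 to 2.667 and 6.136 to 6.158% in mitoT-EC, and 23.30 to 23.33 and 24.42 to 24.45% in mitoAT-EC. These intervals cover counting error only. Folds of genes with 0 to 3 counts in a group used pooled counts, with an exact interval for 1 to 3 counts and a floor of 3 counts for 0. Where 1 mitoAT-EC library was left out, the remaining library was assumed to vary like the others.

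The edgeR steps were tested on simulated data with known changes in the 3 comparisons. Of 66 genes changed 4-fold, 59.1%, 56.1% and 48.5% were recovered. Of 67 changed 2-fold, 8.96%, 2.99% and 7.46% were recovered, and of 1.5-fold changes 0. Every recovered direction was right. Small changes that were not called are therefore not shown to be absent. There were 8, 5 and 3 false calls among 17834, 17859 and 17889 genes. As a share of the calls made, false calls exceeded the adjusted p threshold of 0.05 in each comparison. Called genes can thus include more false calls than that threshold implies. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.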

Results

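RNA sequencing libraries came from human endothelial colony-forming cells (ECFC), primary endothelial cells grown out of progenitors, in a series about mitochondrial transfer, mitophagy and endothelial engraftment. Unprimed-EC (n = 3 libraries) had shared a culture with mesenchymal stromal cells (MSCs) without taking up mitochondria and served as the control. MitoT-EC (n = 3) had taken up MSC mitochondria in coculture, and mitoAT-EC (n = 2) had been given mitochondria by artificial transplantation. The libraries held 18299200 to 30988618 gene counts, except unprimed-EC replicate 3 with 137794637. Principal component 1 (42.7% of the variance) placed the mitoAT-EC libraries at 87.0 and 99.2 and the other 6 libraries between −79.1 and 8.72. The sources used here do not say whether the groups share donors, and the mitoAT-EC contrasts carry any difference of donor or of coculture as well as the transplanted mitochondria.

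Transcripts of the 13 protein-coding genes of mitochondrial DNA (mtDNA), which encode core subunits of the respiratory chain and ATP synthase, took 23.9 ± 0.792% of counts in mitoAT-EC (mean ± SD, n = 2). They took 4.89 ± 1.51% in unprimed-EC (n = 3) and 5.31 ± 2.34% in mitoT-EC (n = 3). The share in mitoAT-EC was 4.88 times that of unprimed-EC (difference 19.0 percentage points) and 4.50 times that of mitoT-EC (18.6 points), each at p = 0.1 in an exact two-sided permutation test. That is the lowest p that 3 libraries against 2 can give. These shares depend on the current titles: with the earlier titles, tried after the data had been seen, they were 18.3% in mitoT-EC and 4.40% in mitoAT-EC. As a share of TPM the 13 genes took 48.3% in mitoAT-EC, against 16.1% in unprimed-EC and 17.8% in mitoT-EC. MitoT-EC and unprimed-EC differed by 0.416 points (exact permutation p = 0.9). This difference turned negative without mitoT-EC replicate 1 (−0.489), unprimed-EC replicate 3 (−0.204) or mitoT-EC replicate 3 (−0.00225), while it was 1.74 without mitoT-EC replicate 2. MALAT1, a long RNA kept in the nucleus, was looked at only after the values had been seen. It took 0.570 ± 0.0870% of counts in mitoAT-EC, 0.177 ± 0.0348% in unprimed-EC and 0.188 ± 0.126% in mitoT-EC.

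**Figure D1:**
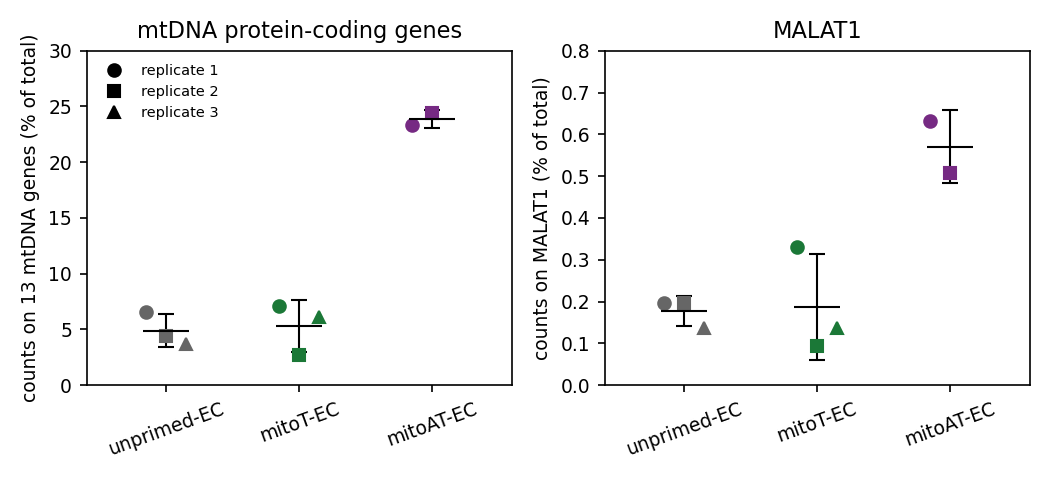
Percentage of gene counts on the 13 protein-coding mtDNA genes in each library, by group.

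HSPE1, which encodes the small chaperonin that works with HSPD1 in the mitochondrial matrix, fell in mitoT-EC against unprimed-EC, from 212 ± 30.2 to 59.6 ± 6.07 CPM (mean ± SD, n = 3 and 3; log2 fold change −1.83 ± 0.17 SE, adjusted p = 0.0267). CKS2, a cofactor of cyclin-dependent kinases, fell from 76.6 ± 12.2 to 27.8 ± 0.692 CPM (−1.46 ± 0.15, adjusted p = 0.0369). These were the only 2 of 18473 genes called, 0 higher and 2 lower, with 3213 genes at unadjusted p < 0.05 in edgeR. The pairing check favoured the replicate numbers as a block but did not establish it. With that block edgeR called 642 genes, 243 higher and 399 lower, with HSPE1 at adjusted p = 0.00474 and CKS2 at 0.00809. With the block and offsets for transcript length and GC content it called 184, 61 higher and 123 lower. Of 41 genes named here that were called only with the block, 24 stayed called with the offsets added and 17 did not. DESeq2 without the block called 810 (245 higher, 565 lower). Both calls were lost with edgeR on the 6 libraries alone (0 genes, 2838 at unadjusted p < 0.05), and CKS2 was lost with offsets for transcript length and GC content (−1.15, adjusted p = 0.0796). Leaving out unprimed-EC replicate 1 gave 220 calls (61 higher). Leaving out unprimed-EC replicate 2, unprimed-EC replicate 3, mitoT-EC replicate 1, mitoT-EC replicate 2 or mitoT-EC replicate 3 gave 0 in edgeR, with 2203, 1889, 2515, 3491 and 3023 genes at unadjusted p < 0.05.

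**Figure D2:**
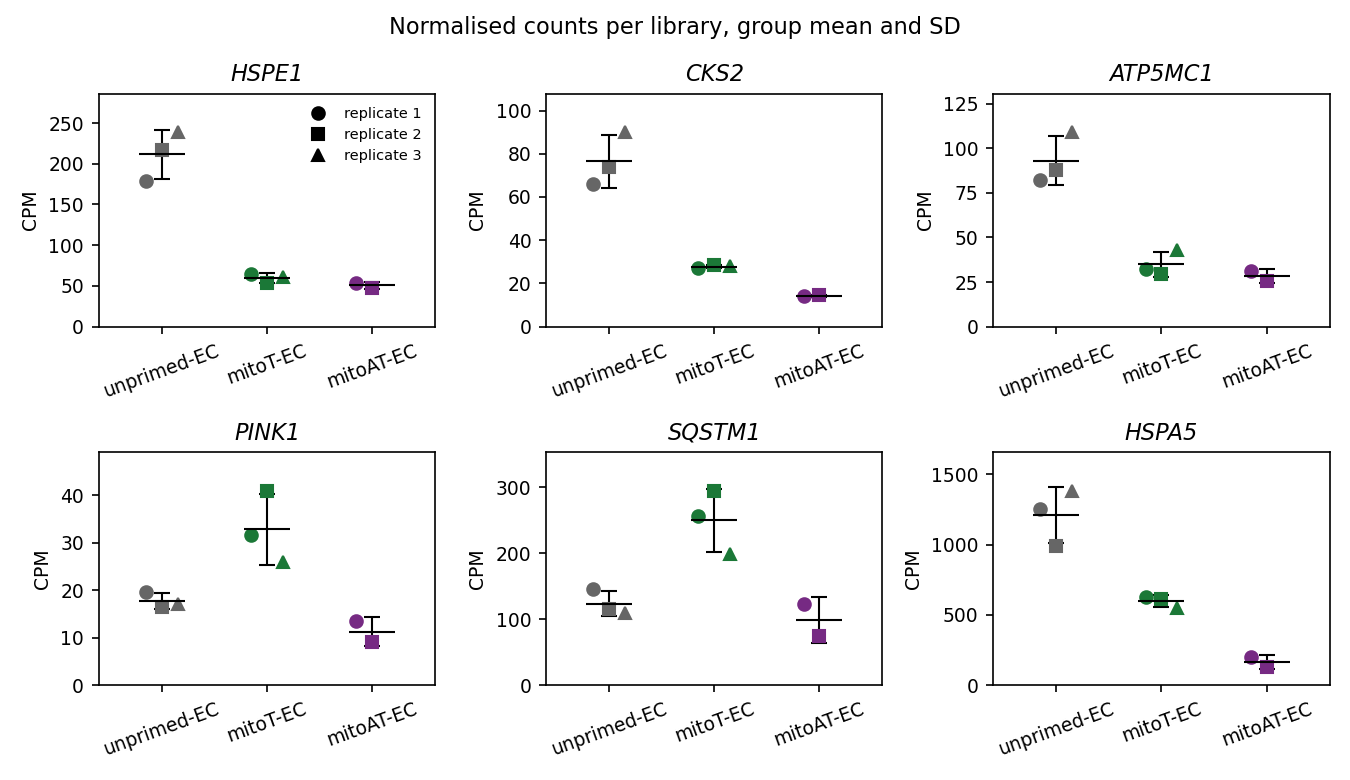
HSPE1, CKS2, ATP5MC1, PINK1, SQSTM1 and HSPA5 in CPM in each library.

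Nuclear genes for the respiratory chain and ATP synthase were lower in mitoT-EC than in unprimed-EC, with a median log2 fold change of −0.68 (quartiles −0.93 to −0.39) over 76 genes. The list was called (camera adjusted p = 8.05e-37, adjusted p = 0.41 with an estimated correlation). Over all genes 0 of the 76 were called and adjusted over the list alone 51 fell. Among these were NDUFB8 of complex I (81.1 ± 12.3 to 32.0 ± 4.42 CPM, −1.34 ± 0.17), COX7B of complex IV (−1.51 ± 0.21) and ATP5MC1 of ATP synthase (−1.42 ± 0.19). With the block 28 of the 76 fell over all genes (adjusted p = 0.0146, 0.0160 and 0.00809 for these 3), and 12 with block and offsets. Mitochondrial ribosomal proteins had a median of −0.49 (adjusted p = 6.72e-19, adjusted p = 0.41 with an estimated correlation). Of these 60 genes 0 fell over all genes, 32 adjusted over the list alone, 16 with the block and 7 with block and offsets, such as MRPL22 (−1.42 ± 0.23) and MRPL17 (−0.97 ± 0.16). Over the 9 other ways to split the same 6 libraries 3 against 3, the largest absolute medians were 0.462 for the respiratory chain list and 0.292 for the mitochondrial ribosome.

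Of the 33 gene lists tested, camera called 11 in mitoT-EC against unprimed-EC, 2 higher and 9 lower, and 12 with the block. The other 9 splits of the 6 libraries gave 8 to 17 called lists, so the number of lists did not set the real grouping apart. With an estimated correlation 0 lists were called (3 at unadjusted p < 0.05, adjusted p = 0.41 to 0.81 for the 11), and fry called 0 (6 at unadjusted p < 0.05).

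Genes of mitosis had a median of −0.52 in mitoT-EC (adjusted p = 0.71 with an estimated correlation). Of 41 genes 0 fell over all genes, 11 adjusted over the list alone, 4 with the block and 1 with block and offsets. Examples were PTTG1, the securin that inhibits separase until anaphase (−1.08 ± 0.16 and adjusted p = 0.0169 with the block), and CDK1 (−1.08 ± 0.24 and adjusted p = 0.0402 with the block). The unfolded protein response of the endoplasmic reticulum had a median of −0.41 (adjusted p = 0.57 with an estimated correlation), with 0 of 21 genes called over all genes, 7 lower adjusted over the list alone, 5 with the block and 3 with block and offsets. Among the 5 with the block were DNAJC3 (−0.91 ± 0.14), SDF2L1 (−1.01 ± 0.20) and MANF (−1.17 ± 0.23), whose fold changes are given without the block. Cytosolic ribosomal proteins such as RPS24 (−0.91 ± 0.23) had a median of −0.45 over 62 genes (adjusted p = 0.71 with an estimated correlation), with 0 called either over all genes or adjusted over the list alone. Interferon-response genes (median −0.51, adjusted p = 0.81 with an estimated correlation) and glycolysis (−0.35, adjusted p = 0.79) also had 0 called in either way. With the block 4 and 2 of them fell (1 and 0 with block and offsets), such as IFI44 (−1.27 ± 0.19, adjusted p = 0.0169) and LDHA (−1.44 ± 0.29, adjusted p = 0.0317). The mitochondrial protein-folding list (median −0.23, adjusted p = 0.41 with an estimated correlation) had HSPE1 as its only member of 15 that fell over all genes or adjusted over the list alone. The integrated stress response had a median of −0.13 (adjusted p = 0.74 with an estimated correlation), with 0 of 34 genes called over all genes and only 1 adjusted over the list alone. DDIT3, a transcription factor of that response, was at −1.16 ± 0.23 with the block (adjusted p = 0.0308).

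**Figure D3:**
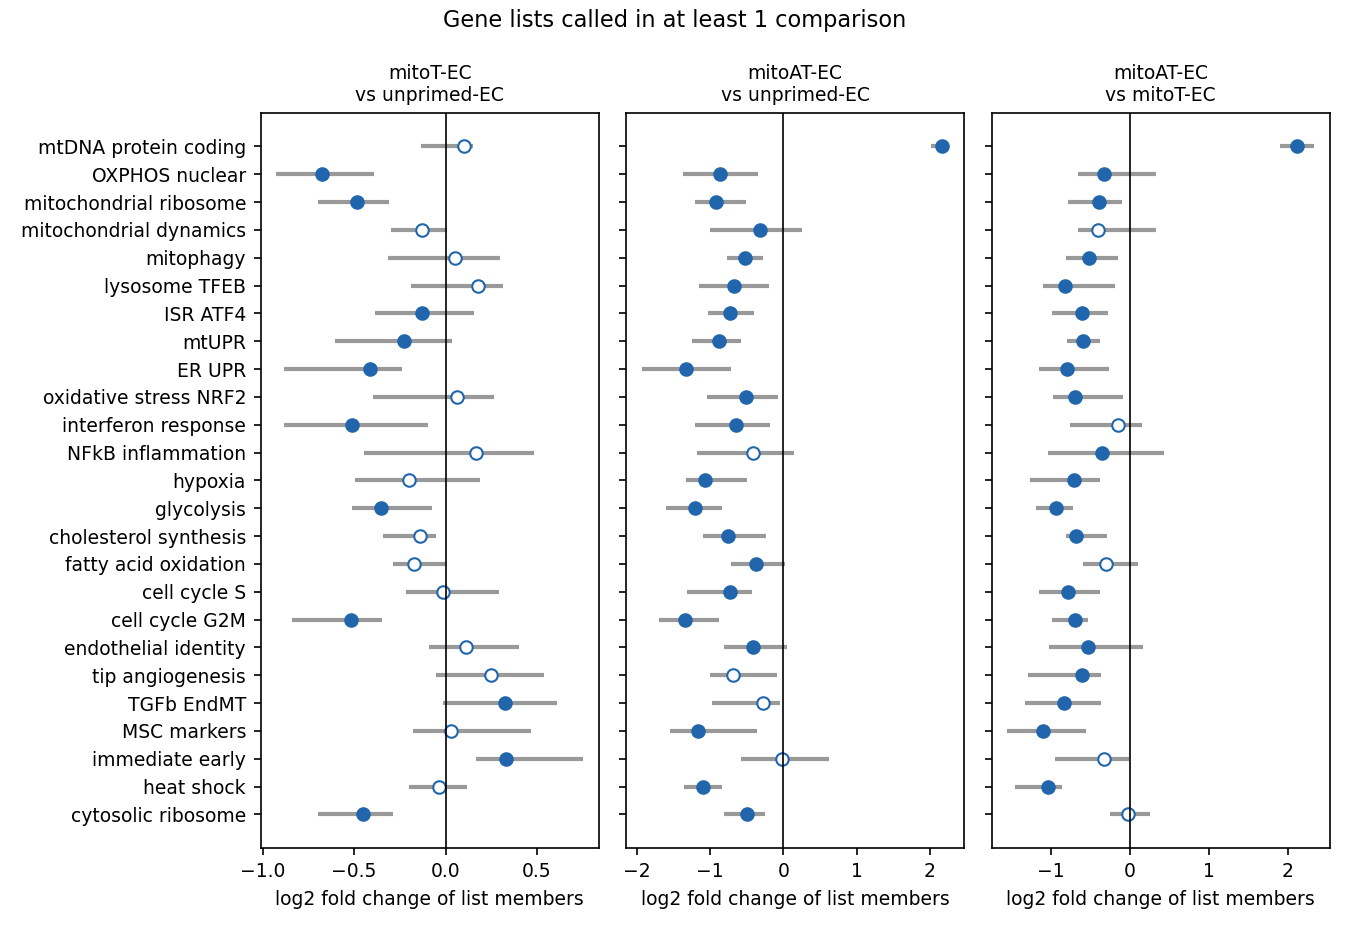
Median log2 fold change of the members of each gene list in the 3 comparisons.

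Immediate early genes had a median of 0.33 in mitoT-EC (adjusted p = 0.57 with an estimated correlation). Of 20 genes 0 rose over all genes and 3 adjusted over the list alone, and with the block 2 rose, MYC (1.13 ± 0.22, adjusted p = 0.0275) and EGR1 (1.26 ± 0.30, adjusted p = 0.0482). Genes of transforming growth factor beta signalling and endothelial-to-mesenchymal transition had a median of 0.32 (adjusted p = 0.71 with an estimated correlation). Of 25 genes 0 rose over all genes, 2 adjusted over the list alone and 2 with the block. They were TGFB1, the growth factor itself (230 ± 59.3 to 700 ± 223 CPM, 1.60 ± 0.28 and adjusted p = 0.0232 with the block), and LTBP2 (0.97 ± 0.20 and adjusted p = 0.0336 with the block). The mitophagy list was not called (camera adjusted p = 0.72), with 0 of 29 genes called over all genes and 4 higher and 3 lower adjusted over the list alone. With the block 3 rose and 0 fell, and with block and offsets 0 were called. PINK1, the kinase that marks damaged mitochondria, stood at 32.8 ± 7.53 against 17.7 ± 1.68 CPM (0.90 ± 0.22, adjusted p = 0.102, with the block 0.0465). The autophagy receptor SQSTM1 stood at 250 ± 48.2 against 124 ± 19.4 CPM (1.02 ± 0.24, adjusted p = 0.0941, with the block 0.0288) and the autophagy kinase ULK1 at 0.79 ± 0.16 (adjusted p = 0.0727, with the block 0.0331). BNIP3 (−0.85 ± 0.37), BNIP3L (0.24 ± 0.21) and TFAM (−0.04 ± 0.19), which packages mtDNA, were not called.

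Endothelial markers PECAM1 (0.42 ± 0.44) and CDH5 (0.42 ± 0.23) were not called in mitoT-EC. The sialomucin EMCN was at −0.99 ± 0.18 with the block (adjusted p = 0.0255), the only gene of the 34 in that list that fell adjusted over the list alone. ICAM1, which binds leukocytes, was at 1.29 ± 0.21 with the block (adjusted p = 0.0206) and ANGPT2, a regulator of vessel sprouting, at 1.28 ± 0.27 (adjusted p = 0.0355). MSC markers had a median of 0.03 over 27 genes and none was called, including COL1A1 (0.91 ± 0.64) and PDGFRB (−0.03 ± 0.34). Among genes called only with the block, the hypoxia-induced MIR210HG (−2.86 ± 0.50), the small GTPase DIRAS3 (−2.12 ± 0.30), the fatty acid carrier FABP4 (27.1 ± 11.5 to 7.37 ± 5.06 CPM, −2.04 ± 0.27) and cyclin CCNA1 (−1.87 ± 0.28) had some of the largest falls. C10orf128 (−2.59 ± 0.43), ELMOD1 (−1.87 ± 0.33) and PYURF (−1.82 ± 0.27) also fell with the block. RPL21P28 (−2.45 ± 0.47) and RPL21P16 (−1.82 ± 0.34) are processed pseudogenes that share sequence with RPL21, so the source of their reads is uncertain.

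Among the genes named here, IRS4, an insulin receptor substrate, had the largest rise with the block in mitoT-EC. It went from 0.0397 ± 0.0456 to 8.22 ± 8.07 CPM (7.75 ± 1.07 with adjusted p = 0.0586, and with the block 7.41 ± 0.47 with 0.000503). The neurofilament gene NEFM (4.04 ± 0.35), the angiomotin gene AMOT (3.61 ± 0.62), the desmosomal cadherin DSG2 (3.80 ± 0.70), the brain-type creatine kinase CKB (2.04 ± 0.35) and the adhesion gene L1CAM (2.08 ± 0.41) also rose with the block (adjusted p = 0.00208, 0.0229, 0.0250, 0.0229 and 0.0294). Further rises with the block were in the steroid dehydrogenase HSD17B2 (1.87 ± 0.30, adjusted p = 0.0184), the kinase PIM1 (1.71 ± 0.25, adjusted p = 0.0161) and the metallothionein MT2A (1.45 ± 0.25, adjusted p = 0.0229). None of these was called in the fit without the block. Adding the offsets to the block ended 17 of the 41 calls made only with the block. The fold changes fell by more than 1 SE in 4 of them: CDK1 −1.08 ± 0.24 to −0.71 ± 0.26, LTBP2 0.97 ± 0.20 to 0.65 ± 0.19, ULK1 0.79 ± 0.16 to 0.54 ± 0.14 and EMCN −0.99 ± 0.18 to −0.77 ± 0.17 (adjusted p = 0.193, 0.127, 0.0987 and 0.0635). In the other 13 they moved by less than 1 SE, and in 3 of these they grew. The 13 included DSG2 3.80 ± 0.70 to 3.76 ± 0.74, CKB 2.04 ± 0.35 to 2.06 ± 0.40, MT2A 1.45 ± 0.25 to 1.54 ± 0.30, L1CAM 2.08 ± 0.41 to 1.84 ± 0.38, ELMOD1 −1.87 ± 0.33 to −1.71 ± 0.33, RPL21P16 −1.82 ± 0.34 to −1.56 ± 0.32 and ANGPT2 1.28 ± 0.27 to 1.35 ± 0.27 (adjusted p = 0.05025, 0.0502, 0.05025, 0.0563, 0.0502, 0.0567 and 0.0515). The rest were SDF2L1 −0.997 ± 0.15 to −0.95 ± 0.19, LDHA −1.44 ± 0.29 to −1.28 ± 0.30, DDIT3 −1.16 ± 0.23 to −1.03 ± 0.21, EGR1 1.26 ± 0.30 to 1.18 ± 0.31, SQSTM1 1.02 ± 0.20 to 0.95 ± 0.19 and PINK1 0.88 ± 0.21 to 0.78 ± 0.19 (adjusted p = 0.0542, 0.0737, 0.0563, 0.0987, 0.0557 and 0.0891). The largest unadjusted p among called genes went from 0.00174 with the block to 0.000494 with block and offsets. Of the 13, 10 still had an unadjusted p below 0.00174. The unadjusted p of these 10 also rose with the offsets, such as SDF2L1 from 4.93e-05 to 0.000745 and CKB from 0.000137 to 0.000535. Apart from ANGPT2 (0.000638 to 0.000650), their p with the block lay below 0.000494. For those genes the stricter limit alone did not end the calls.

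IRS4 stood at 2.48, 17.5 and 4.74 CPM in mitoT-EC replicates 1 to 3, at no more than 0.0895 in unprimed-EC and at 0 in mitoAT-EC. A further 8 genes that are high in the kidney cell line HEK293 were fixed after IRS4 and NEFM had been seen and before their own values were. Of these, 6 were higher in every mitoT-EC library than in all 5 others: LIN28B, NEFL, ELAVL2, SOX11, IGF2BP1 and ZIC2. ELAVL2 met this narrowly, with 0.273 CPM in mitoT-EC replicate 3 against 0.268 in mitoAT-EC replicate 1 (5 counts each). IGF2BP1 was expressed in all libraries (44.3 to 57.8 CPM against 32.0 to 40.9). GAL and TUBB2B did not meet it, with 6.05 and 7.97 CPM in unprimed-EC replicate 1 and at most 4.26 and 6.87 in mitoT-EC.

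**Figure D4:**
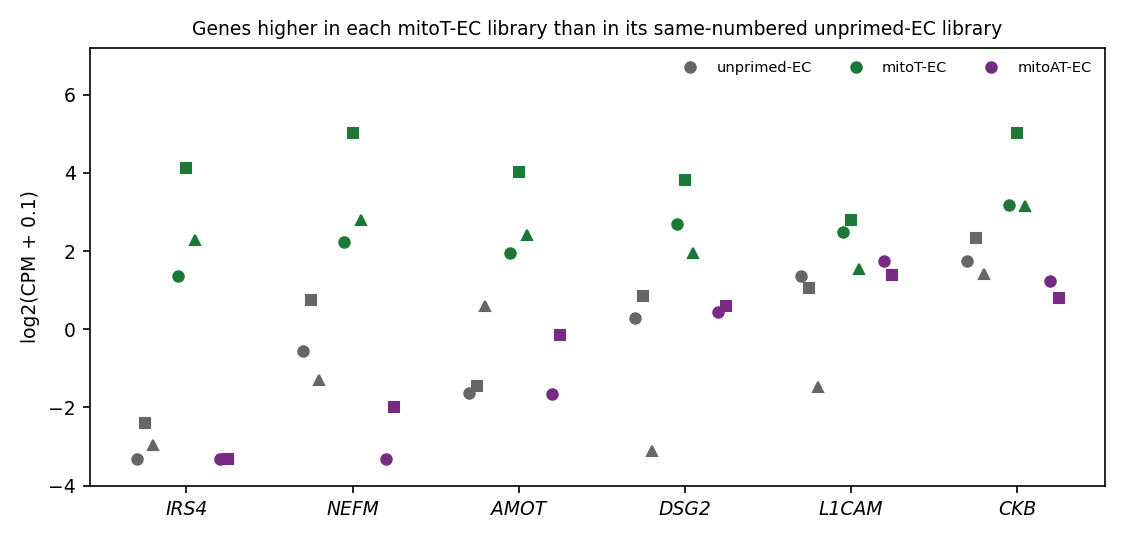
IRS4, NEFM, AMOT, DSG2, L1CAM and CKB in each library, as log2 of CPM plus 0.1.

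All 13 protein-coding mtDNA genes rose in mitoAT-EC (n = 2) against unprimed-EC (n = 3), with a median log2 fold change of 2.16 (camera adjusted p = 8.69e-15, adjusted p = 0.34 with an estimated correlation), both over all genes and adjusted over the list alone. MT-CO1, the catalytic subunit of complex IV, rose by 2.55 ± 0.49 (17350 to 101730 CPM) and MT-CYB of complex III by 2.16 ± 0.38. MT-ND6 rose by 2.64 ± 0.48, although its antisense position leaves its reads uncertain where the strand setting is not given. On deposited TPM with a pseudocount of 0.1, MT-CO1 rose by 1.94 and its call was lost (adjusted p = 0.0544). On TPM with a pseudocount of 1 and no filter, MT-CO1, MT-ND6 and MT-CYB were not called (adjusted p = 0.657, 0.244 and 0.256). Nuclear genes for the same complexes moved the other way. Of 76 respiratory chain and ATP synthase genes 47 fell and 0 rose over all genes, and 50 fell and 1 rose adjusted over the list alone (median −0.87, adjusted p = 0.34 with an estimated correlation). ATP5MC3 (−1.93 ± 0.21) and SDHD (−1.71 ± 0.19) were among them. Mitochondrial ribosomal proteins fell as well, 40 of 60 over all genes with 1 higher and 48 with 1 higher adjusted over the list alone (median −0.91, adjusted p = 0.34 with an estimated correlation). They included MRPS28 (−2.04 ± 0.26) and MRPL17 (−1.40 ± 0.18). TFAM fell by 0.76 ± 0.22 (adjusted p = 0.0352), a call lost without unprimed-EC replicate 1, 2 or 3 (adjusted p = 0.0705, 0.0544 and 0.106). The mitochondrial chaperones HSPE1 and HSPD1 fell by 2.06 ± 0.20 and 2.02 ± 0.24.

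In mitoAT-EC against unprimed-EC 4178 of 18473 genes were called, 1872 higher and 2306 lower (44.8% higher). Of these 2707 changed at least 2-fold. Without the expression filter 26.4% were higher (5410 calls), and with deposited TPM and limma 6.83%, 9.76% and 9.51% under 3 settings (6540, 6517 and 5143 calls). TPM were not scaled for composition, and mtDNA genes took 48.3% of TPM in mitoAT-EC against 16.1% in unprimed-EC. With the filter the median log2 fold change of all genes on TPM was −0.54 and −0.40, against 0.05 in the main fit. The TPM settings thus shift genes downward and do not bear on direction. Rises lost on TPM carry the same shift. MT-CO1, however, rose by 1.94 both with the filter and a pseudocount of 0.1 and without the filter at a pseudocount of 1. Its limma adjusted p was 0.0544 and 0.657, so the shift alone does not account for its loss without the filter. Size factors by RLE and by library size alone left the split at 43.2% and 40.02%. Leaving out unprimed-EC replicate 2 gave 2664 calls, unprimed-EC replicate 3 1503 (30.1% higher), and mitoAT-EC replicate 1 1499. Leaving out mitoAT-EC replicate 2 gave 0 in edgeR, with 4609 genes at unadjusted p < 0.05, where DESeq2 on all libraries called 4947. With groups taken from the earlier sample titles edgeR called 0 (1936 at unadjusted p < 0.05).

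The endoplasmic reticulum chaperone HSPA5 fell from 1210 ± 198 CPM in unprimed-EC to 164 ± 47.9 in mitoAT-EC (−2.88 ± 0.28, adjusted p = 0.00426), PDIA3 by 2.37 ± 0.27 and MANF by 2.32 ± 0.28. In that list 17 of 21 genes fell over all genes, and 18 fell and 1 rose adjusted over the list alone (median −1.32, adjusted p = 0.34 with an estimated correlation). Of 41 genes of mitosis 30 fell over all genes and 33 adjusted over the list alone (median −1.35, adjusted p = 0.34 with an estimated correlation), such as DLGAP5 (−2.82 ± 0.33) and CCNB1 (−2.28 ± 0.35). The glycolytic enzymes LDHA (−2.80 ± 0.46) and PGK1 (−2.20 ± 0.33) fell with 12 of 23 genes of their list over all genes and 15 adjusted over the list alone (median −1.20, adjusted p = 0.35 with an estimated correlation). The lysosomal genes LAMP2 (−1.76 ± 0.28) and CTSL (−1.44 ± 0.24) stood for 18 of 43 that fell and 1 that rose over all genes, and 21 and 1 adjusted over the list alone (median −0.67, adjusted p = 0.34 with an estimated correlation). The peroxide-removing PRDX1 (−2.18 ± 0.28), the stress-induced DDIT4 (−2.70 ± 0.38) and the sterol enzymes NSDHL (−1.54 ± 0.21) and SQLE (−1.44 ± 0.23) also fell.

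Of 33 lists camera called 21 in mitoAT-EC against unprimed-EC, 1 higher and 20 lower, fry called 18 (16 of the 21) and camera with an estimated correlation 0 (3 at unadjusted p < 0.05, adjusted p = 0.23 to 0.67). The mitophagy list was lower (median −0.52, adjusted p = 0.000613, adjusted p = 0.37 with an estimated correlation), with 7 of 29 genes lower and 1 higher over all genes, and 10 and 1 adjusted over the list alone. The outer-membrane channel VDAC1 (−1.47 ± 0.27), PHB2 (−0.98 ± 0.21) and the hypoxia-induced receptor BNIP3 (−1.62 ± 0.43, adjusted p = 0.0279) fell. PHB2 was not called without unprimed-EC replicate 3 (adjusted p = 0.050005). ULK1 rose by 0.89 ± 0.17 (0.64 and adjusted p = 0.0613 without the expression filter). On deposited TPM ULK1 was not called either (adjusted p = 0.277, 0.292 and 0.312 under 3 settings). PINK1 (−0.65 ± 0.25, adjusted p = 0.0892), SQSTM1 (−0.33 ± 0.27) and BNIP3L (−0.54 ± 0.24) were not called. PPARGC1A, a regulator of mitochondrial biogenesis, had 0 to 6 counts per library and was not tested.

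The cytokine gene IL1B fell in mitoAT-EC against unprimed-EC to 2 counts, 108-fold in pooled counts (29.7 to 890-fold from counting alone). The oxygen-binding CYGB fell 126-fold (43.0 to 611-fold), the microfibril gene MFAP5 32.9-fold (11.2 to 160-fold) and the hyaluronan synthase HAS2 by 5.28 ± 0.64 (20.2 ± 12 to 0.512 ± 0.336 CPM). The matrix proteinase MMP3 (−4.74 ± 0.55), the stromal and pericyte marker CD248 (−4.47 ± 0.45) and the chemokine CXCL6 (−4.09 ± 0.83) fell too. So did the proteinase gene PAPPA (−5.08 ± 1.47), the matrix gene SPON2 (−3.79 ± 0.82) and the transcription factor TBX2 (−3.77 ± 0.76). MFAP5 was close to the threshold (adjusted p = 0.0479) and was lost with length and GC offsets (adjusted p = 0.0587), with nuclear protein-coding genes alone (adjusted p = 0.0553). It was also lost without any single unprimed-EC library (replicates 1 to 3: adjusted p = 0.0897, 0.0772 and 0.0528). PAPPA was lost without unprimed-EC replicate 1 (adjusted p = 0.0711) or replicate 2 (0.0610). On deposited TPM with a pseudocount of 1, MFAP5 and PAPPA were not called (adjusted p = 0.162 and 0.127), and without the filter neither were MFAP5, PAPPA, CYGB and SPON2 (adjusted p = 0.322, 0.275, 0.0797 and 0.0605). Pooled folds with each library left out were computed after the data had been seen. CYGB fell 41.6-fold without unprimed-EC replicate 3, which held 1634 of its 1780 counts, and MFAP5 fell 21.8-fold without replicate 1 and 89.6-fold without replicate 3.

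Markers of MSCs moved in the same direction in mitoAT-EC. PDGFRB, a receptor of stromal cells and pericytes, fell from 26.7 ± 10.6 to 4.40 ± 1.84 CPM (−2.61 ± 0.44), NT5E by 1.56 ± 0.33, COL6A1 by 1.16 ± 0.26 and the pericyte gene NOTCH3 by 3.04 ± 0.43. Of the 27 markers 7 fell over all genes and 12 adjusted over the list alone (median −1.16, adjusted p = 0.37 with an estimated correlation). DCN (0.31 ± 0.87), LUM (0.37 ± 0.92), PDGFRA (0.07 ± 0.93) and COL1A1 (−0.38 ± 0.71) were not called. Unprimed-EC had shared a culture with MSCs. Whether the falls of stromal genes, such as PDGFRB and CD248, arose in the endothelial cells or from MSC RNA in the cocultured libraries was not tested. Endothelial markers had a median of −0.41 (adjusted p = 0.49 with an estimated correlation), with 7 of 34 lower over all genes and 4 adjusted over the list alone. They included ICAM2 (−1.51 ± 0.24), MMRN1 (−2.09 ± 0.51) and MCAM (−1.05 ± 0.29). Without unprimed-EC replicate 3 COL6A1, MMRN1 and MCAM were not called (adjusted p = 0.0593, 0.0529 and 0.101), and MCAM was also lost without replicate 1 (0.0557). PECAM1 (−0.85 ± 0.51) and CDH5 (−0.30 ± 0.26) were not called. With the block the endothelial list was no longer called (adjusted p = 0.0564, with block and offsets 0.0825), while it was with offsets alone (0.0325).

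Non-coding and unprocessed transcripts made up the largest rises in mitoAT-EC against unprimed-EC. The unclassified transcript AL136164.3 rose from 1.92 ± 0.785 to 22.4 ± 3.69 CPM (3.57 ± 0.63), the small Cajal body RNA SCARNA7 by 2.96 ± 0.48 and MALAT1 by 1.72 ± 0.45 (adjusted p = 0.0270). MALAT1 was not called without unprimed-EC replicate 1, 2 or 3 (adjusted p = 0.0514, 0.0581 and 0.0927) or on deposited TPM (0.0888, 0.0853 and 0.198 under 3 settings). MFSD13B and AC058791.1 were lost on TPM without the filter (adjusted p = 0.0551 and 0.0810). The lincRNA genes AC058791.1 (2.89 ± 0.68, adjusted p = 0.0604 without unprimed-EC replicate 3), AC234772.3 (2.84 ± 0.45) and a Y RNA gene of the RF00019 family (3.01 ± 0.54, adjusted p = 0.0815 with length and GC offsets) rose. The antisense AL451042.2 (3.27 ± 0.42) and the pseudogenes MFSD13B (3.31 ± 0.68), CR788268.1 (3.26 ± 0.52) and CYP51A1P3 (3.07 ± 0.50) also rose. Reads of the antisense gene and of the pseudogenes can come from the opposite strand or the parent genes. MTCO1P12, a pseudogene that shares reads with MT-CO1, rose by 2.82 ± 0.41. Sense intronic genes, transcripts inside introns, had a median of 1.22 (74 rose and 1 fell of 298), small nuclear RNA genes 2.01 (25 rose and 0 fell of 54) and processed pseudogenes 0.99 (129 rose and 24 fell of 710). Protein-coding genes had a median of −0.13 (1021 rose and 2226 fell of 13642). The rise of mtDNA, intronic and small nuclear transcripts went with the fall of the mitochondrial, secretory, mitotic and glycolytic mRNA groups in the same 2 libraries.

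PINK1 fell in mitoAT-EC (n = 2) against mitoT-EC (n = 3), from 32.8 ± 7.53 to 11.3 ± 3.08 CPM (−1.54 ± 0.26, adjusted p = 0.0136), and SQSTM1 from 250 ± 48.2 to 98.5 ± 34.6 CPM (−1.34 ± 0.28, adjusted p = 0.0178). With the mitochondrial ubiquitin ligase MUL1 (−1.38 ± 0.25) and VDAC1 (−1.26 ± 0.27) they were among 9 of 29 mitophagy genes that fell over all genes and 12 adjusted over the list alone, with 0 higher (median −0.52, adjusted p = 0.40 with an estimated correlation). BNIP3 (−0.77 ± 0.42), BNIP3L (−0.78 ± 0.24, adjusted p = 0.0552) and TFAM (−0.73 ± 0.22, adjusted p = 0.0502) were not called. Lysosomal genes fell, 23 of 43 over all genes, and 26 with 2 higher adjusted over the list alone (median −0.83, adjusted p = 0.38 with an estimated correlation). Examples are the hydrolase GLB1 (−1.79 ± 0.27) and the membrane protein LAMP2 (−1.82 ± 0.29). GABARAP, which builds the autophagosome membrane, fell by 1.66 ± 0.21, while VMP1, needed for autophagosome formation, rose by 1.31 ± 0.21. All 13 mtDNA genes rose over all genes and adjusted over the list alone (median 2.11, adjusted p = 0.38 with an estimated correlation), such as MT-ND3 (2.5 ± 0.38) and MT-CO2 (2.41 ± 0.41). MT-CO1 rose by 2.34 ± 0.49 and was not called on deposited TPM (1.67, adjusted p = 0.0778 with a pseudocount of 0.1 and 0.0507 with 1). On TPM without the filter MT-CO1, MT-ND3 and MT-CO2 were not called (adjusted p = 0.660, 0.134 and 0.405).

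Nuclear respiratory chain genes were mixed in mitoAT-EC against mitoT-EC, 17 lower and 7 higher of 76 over all genes, and 23 and 11 adjusted over the list alone (median −0.33, adjusted p = 0.61 with an estimated correlation). The list was lost with the block (adjusted p = 0.147) and called with offsets (adjusted p = 2.26e-05) or block and offsets (adjusted p = 0.000489). SDHB (−1.36 ± 0.21) and COX5A (−1.51 ± 0.24) fell. Of 25 genes of transforming growth factor beta signalling 8 fell and 1 rose over all genes, and 11 and 2 adjusted over the list alone (median −0.83, adjusted p = 0.40 with an estimated correlation). TGFB1 was at −1.79 ± 0.32 and its target ID2 at −2.17 ± 0.51. PDIA6 (−2.96 ± 0.47), HSPA5 (−1.87 ± 0.26) and PGK1 (−1.82 ± 0.32) fell with the secretory and glycolytic lists. In these lists 8 of 21 and 11 of 23 genes fell over all genes and 13 and 13 adjusted over the list alone (adjusted p = 0.40 with an estimated correlation for each). PDGFRB fell by 2.58 ± 0.44 and ICAM1 by 1.97 ± 0.24, and COL1A1 (−1.29 ± 0.74), PECAM1 (−1.26 ± 0.51) and CDH5 (−0.72 ± 0.27) were not called. IRS4 fell at least 110-fold, to 0 counts, IL1B 230-fold (63.4 to 1900-fold from counting alone) and NEFM 200-fold (68.2 to 970-fold). MFAP5 fell 119-fold (40.5 to 578-fold), CYGB 60.3-fold (20.5 to 294-fold), and falls were also seen in PAPPA (−5.83 ± 1.5), MMP3 (−4.45 ± 0.55), HAS2 (−4.23 ± 0.62), AMOT (−4.02 ± 1.06) and the natriuretic peptide receptor NPR3 (−3.97 ± 1.05). Without mitoT-EC replicate 2 PAPPA, ID2, MFAP5, AMOT and NPR3 were not called (adjusted p = 0.0781, 0.0547, 0.0973, 0.0867 and 0.0880), and without mitoT-EC replicate 1 MFAP5 and NPR3 were not (0.0593 and 0.0537). With these 2 groups alone MFAP5 and NPR3 were also lost (adjusted p = 0.0550 and 0.0509). On TPM without the filter so were PAPPA, MFAP5, CYGB, AMOT and NPR3 (adjusted p = 0.155, 0.215, 0.0597, 0.0554 and 0.127), and with the filter PAPPA, MFAP5 and NPR3 (adjusted p = 0.0632, 0.0962 and 0.0501). The folds of IRS4 and NEFM leaned on mitoT-EC replicate 2, with 536 of 702 and 1001 of 1275 counts. Without it IRS4 fell at least 41.8-fold and NEFM 68.9-fold. Without mitoT-EC replicate 3 CYGB fell 39.2-fold and MFAP5 152-fold. That library held only 3 of the 759 MFAP5 counts of mitoT-EC, so the 119-fold value describes replicates 1 and 2. Rises in mitoAT-EC against mitoT-EC were seen in non-coding genes: the pseudogene AC144530.1 (4.63 ± 0.58), the RF00019 Y RNA gene (3.55 ± 0.56, adjusted p = 0.0504 with length and GC offsets), SCARNA7 (3.52 ± 0.49) and AC234772.3 (3.37 ± 0.46). They were followed by MIR604 (3.30 ± 0.71), AL136164.3 (3.25 ± 0.62) and AC048341.2 (3.23 ± 0.32). Also higher were AC091057.2 (3.07 ± 0.80, adjusted p = 0.110 with the offsets and 0.0859 without mitoT-EC replicate 2), the mitochondrial transfer RNA MT-TC (3.04 ± 0.41, adjusted p = 0.0545 on TPM without the filter) and the pseudogene CBWD4P (2.95 ± 0.59).

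In mitoAT-EC against mitoT-EC 3084 of 18473 genes were called, 1354 higher and 1730 lower (43.9% higher), of which 1933 changed at least 2-fold (51.0% higher). Without the expression filter 31.1% were higher (4506 calls) and with deposited TPM 6.03%, 8.31% and 8.36% (7883, 7892 and 6601 calls). The downward shift of TPM applies here too, with filtered medians over all genes of −0.71 and −0.55 against −0.03 in the main fit. EdgeR called 1706 with these 2 groups alone, 1523 without mitoT-EC replicate 2, 546 without mitoAT-EC replicate 1 (59.9% higher) and 0 without mitoAT-EC replicate 2 (3641 at unadjusted p < 0.05). DESeq2 called 4019 on all libraries. With the earlier sample titles edgeR called 0 (4499 at unadjusted p < 0.05). Camera called 20 lists of 33, 1 higher and 19 lower, fry 13 and camera with an estimated correlation 0 (4 at unadjusted p < 0.05, adjusted p = 0.38 to 0.61).

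The fold changes of mitoT-EC and of mitoAT-EC against the same unprimed-EC libraries correlated at 0.305 across 18473 genes. In 40 simulations of unchanged groups sharing their controls the mean was 0.421 (0.397 to 0.449) without pairing. It was 0.328 (0.301 to 0.365) with mitoT-EC and unprimed-EC libraries paired. The many real changes in mitoAT-EC widen the spread of its fold changes and can lower a correlation. Neither range therefore shows what correlation shared controls alone would give here. With the block the correlation was 0.256, against 0.324 (0.293 to 0.357) in the paired simulations, where the same limit holds. The covariance, 0.213, was larger than the simulated 0.109 and 0.0662, but was 0.0279 without mitoT-EC replicate 1 and 0.359 without mitoT-EC replicate 2. The correlation ran from 0.0365 without mitoT-EC replicate 1 to 0.503 without mitoT-EC replicate 2. HSPE1 fell in both, and with the block 250 genes were lower in both comparisons (61.7 for independent calls, 4 in opposite directions) and 65 were higher in both (31.8, 7 in opposite directions). Among as many top genes in the simulations with pairing, 159 (139 to 177) were lower in both and 119 (99 to 134) higher in both. The simulations left mitoAT-EC unchanged, while 5274 genes were called in it with the block. They therefore cannot show what overlap shared controls would give here. The block also pairs mitoAT-EC by number, which the pairing check did not show. Called genes shared in the same direction numbered at most 1 in these simulations. The 3 control libraries cannot give each of the 2 comparisons 2 libraries of its own, and an unequal division was not tried.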

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

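Chosen after seeing the data were the length and GC offsets (alone or with the block), the block on 2 groups, the block with an estimated correlation, the thinning of unprimed-EC replicate 3, nuclear protein-coding genes alone, pooled folds with 1 library left out, earlier titles for the mtDNA share, simulated groups with pairing, and the block and offsets for the correlation of fold changes; the other settings were fixed before.

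Genes called in mitoT-EC against unprimed-EC numbered 2. The replicate block gave 642, the block on 2 groups 1178, length and GC offsets 1, block and offsets 184, nuclear protein-coding genes 88, no filter 1020, DESeq2 810. The 2 groups alone gave 0, earlier titles 767, and TPM with a pseudocount of 1 0 with or without the filter. Leaving out 1 library gave 0 to 220. HSPE1 and CKS2 were lost in 6 and 7 of the counts-based settings, among them the 5 left-out libraries that gave 0.

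Genes called in mitoAT-EC against unprimed-EC numbered 4178. With the block they numbered 5274, at least 2-fold 2707, with TPM 6540 and 6517, with earlier titles 0, and with 1 library left out 0 to 3292. In mitoAT-EC against mitoT-EC they numbered 3084. With the block they numbered 4531, at least 2-fold 1933, with 2 groups alone 1706, with TPM 7883, 7892 and 6601 (the last without a filter), with earlier titles 0, and with 1 library left out 0 to 3340. Size factors by RLE, library size, leaving out mtDNA genes, a stricter filter, offsets and nuclear protein-coding genes alone stayed within 1.5-fold for these 2 comparisons. Without mitoAT-EC replicate 2, 0 of 55 and 0 of 40 named calls remained, and without replicate 1 40 and 21. No named call turned around except with the earlier titles.

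Lists called numbered 11, 21 and 20 (mitoT-EC against unprimed-EC, mitoAT-EC against unprimed-EC, mitoAT-EC against mitoT-EC). The block gave 12, 24 and 21, an estimated correlation 0, 0 and 0, the block with an estimated correlation 0, 0 and 0, and fry 0, 18 and 13. Earlier titles gave 21, 10 and 19 (the last with 18 higher and 1 lower), and 1 left-out library 9 to 13, 19 to 24 and 20 to 22.

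The mtDNA share difference of mitoT-EC and unprimed-EC, 0.416 points, ran from −0.489 to 1.74 with 1 library left out and was −0.204 without unprimed-EC replicate 3 and −0.00225 without mitoT-EC replicate 3. It was 19.0 (18.4 to 19.8) for mitoAT-EC against unprimed-EC and 18.6 (17.2 to 19.5) against mitoT-EC, and as a share of TPM 1.72, 32.3 and 30.6. With the earlier titles the 3 differences were 13.4, −0.489 and −13.9 points, since the libraries change groups. The correlation of fold changes, 0.305, was 0.50 over genes called in either comparison, 0.434 at 10 CPM or more, 0.256 with the block, 0.321 with offsets and 0.0365 to 0.503 with 1 library left out.

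With the earlier titles 18 of 55 named calls of mitoAT-EC against unprimed-EC changed sign without being called: IL1B 0.81, CYGB 0.14, MFAP5 0.38, PAPPA 0.51, AL136164.3 −0.80, SCARNA7 −1.06, MT-ND6 −0.20, LAMP2 0.19, TFAM 0.0789, NT5E 0.12, COL6A1 0.01002, MMRN1 0.25, MCAM 0.34, MALAT1 −0.59, SPON2 0.36, RF00019 −0.27, AC058791.1 −0.21 and AC234772.3 −0.83. All 40 of mitoAT-EC against mitoT-EC did: IRS4 3.65, IL1B 1.43, NEFM 3.56, PAPPA 0.91, MMP3 1.72, HAS2 1.06, AC144530.1 −4.64, SCARNA7 −3.53, MT-CO1 −2.10, MT-ND3 −2.44, MT-CO2 −2.14, SDHB 0.94, COX5A 1.08, PINK1 0.89, SQSTM1 0.71, MUL1 0.99, VDAC1 0.78, GLB1 1.33, LAMP2 1.25, PDIA6 1.55, HSPA5 0.87, PGK1 1.35, TGFB1 1.40, ID2 1.17, PDGFRB 0.99, ICAM1 1.12, GABARAP 0.99, VMP1 −1.08, MFAP5 0.74, CYGB 2.71, AMOT 2.71, NPR3 0.68, RF00019 −2.72, AC234772.3 −3.18, MIR604 −4.09, AL136164.3 −3.92, AC048341.2 −2.99, AC091057.2 −2.23, MT-TC −2.98 and CBWD4P −2.48.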

Other observations

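The tests of mtDNA carried over as DNA, of a lower share of cytosolic mRNA, of length and GC content, of MSC RNA and of the gene counts in other splits were chosen after seeing the results; those of genomic DNA, of depth, of HEK293-type RNA and of list counts in other splits were set before their values were looked at.

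mtDNA transcripts were 4.88 times as large a share in mitoAT-EC as in unprimed-EC. DNA of the transplanted mitochondria in the libraries would add reads evenly along the mtDNA. MT-CO1, however, gained 6.43 times as many CPM per kilobase as the median of 5 other mtDNA genes (5.81 and 6.43 in mitoAT-EC replicates 1 and 2). This argues against DNA as the main source. Among those 5 genes the highest gain was 2.33 times the lowest. Over all 13 genes it was 14.6 times, but reads shared with nuclear copies can lower the gain of single genes. Cellular DNA would also bring mtDNA reads evenly, so the MT-CO1 values argue against it as the main source, while its own test was undecided. In that test 369 olfactory receptor genes, silent in most cells, summed to 1.55 CPM in mitoAT-EC and 0.839 in the cocultured libraries. The ratio was 1.85 with overlapping ranges. A lower share of cytosolic mRNA in the RNA could also raise mitochondrial, nuclear and intronic transcripts together, and it stays open, because the median log2 fold change of sense intronic genes, 1.22, had been seen before this explanation was considered. More mitochondria per cell after the transplantation was not tested by these data and would not by itself raise intronic transcripts.

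Nuclear respiratory chain and mitochondrial ribosome genes were lower in mitoT-EC. With the block and offsets for transcript length and GC content the medians were −0.52 (SE 0.040) and −0.36 (SE 0.045). Both lay below a bound of −0.1 set after the values were seen. Without unprimed-EC replicate 3, the deepest library, the respiratory chain median was −0.59 (SE 0.042). The offsets and the removal of that library thus left the medians low. These SEs treat the genes of a list as independent, although their estimated correlations were 0.315 and 0.224. They also leave out the spread between libraries, so they cannot exclude length and GC content as the whole cause, or depth. Over the 10 ways to split the 6 libraries, 1 gave as many called genes as the real 2 (highest other 1), 1 gave as many with the block as the real 642 (highest other 0, also in the 3 other splits that part all 3 pairs), 7 gave as many lists as the real 11 (highest other 17) and 7 as many with the block as the real 12 (highest other 18). With 10 splits the share cannot fall below 0.1. A response of the cells to the mitochondria they received remains possible and was not tested beyond these comparisons.

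IRS4, NEFM, AMOT, DSG2, L1CAM and CKB were higher in mitoT-EC. RNA of HEK293-type cells, a line used to make viral vectors, might explain this: 6 of 8 markers of HEK293 were higher in every mitoT-EC library than in the 5 others (ELAVL2 narrowly), with LIN28B at 0.581, 4.14 and 1.64 CPM in the order that IRS4 followed. More MSC RNA in mitoT-EC is undecided, because MSC markers had a median of 0.0314 (SE 0.128) while these 6 genes are not among them. Induction of the genes in the endothelial cells themselves was not tested, and the labels name no HEK293 cells.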
